A study of Mus musculus with 9 samples.

How the data were processed

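RNA was measured in 9 libraries of mouse embryonic stem cells of the line CCE in which the gene for RNF12 had been disrupted with CRISPR/Cas9. Per the labels, the cells were transfected by lipofection with an empty vector, with wild-type RNF12 or with the catalytic mutant RNF12 W576Y, 3 libraries each, and total RNA was made into stranded libraries. Groups and replicate numbers were taken from the sample titles. The labels do not say whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

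The authors deposited read counts per gene symbol, as whole numbers, in both of their comparison tables, and the counts of the 3 wild-type libraries were identical in the 2 tables. Per the submitters' processing notes, the tools named were STAR 2.7.1a, HTSeq 0.11.2 and DESeq2 1.24, and the build was mm10. The annotation used for counting and its strand setting are not given in the sources used here. The authors' deposited tables also hold log2 fold changes and adjusted p-values from their own 2 comparisons, each with 6 libraries per the file headers. Those log2 values and p-values were used only to set the authors' call counts beside the ones computed here.

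The tables held 23420 gene symbols, of which 4154 had no read in any library. Total counts ranged from 37852339 to 54641514 per library, and the most abundant gene, Eef1a1, took 1.13% to 1.32% of them. Of the symbols, 99.3% matched a RefSeq gene of GRCm38.p6 by symbol or synonym and 174 did not. Chromosomes came from that match, and printed positions are those of GENCODE M21 on GRCm38, the assembly behind mm10, counted from 1. No row without a gene name was present.

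Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 15121, library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 9 libraries, leaving 6 residual degrees of freedom. Each of the 3 comparisons was tested with glmQLFTest, and p-values were adjusted over genes by Benjamini-Hochberg, with a threshold of 0.05. Expression levels are TMM-scaled counts relative to library size, in the unit CPM, given as mean ± SD. The SE of a log2 fold change is its size divided by the square root of the F statistic. Activity-dependent genes were those past the threshold in both comparisons that involve the wild-type libraries, with opposite signs. The overlap was set beside that in 20 simulated data sets without group effects and that of independent lists.

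Of 21 gene lists fixed before the data were examined, 20 had members that could be tested. The list of mitochondrially encoded genes was not analysed here. Lists and the X-linked genes other than Xist, Tsix and Rlim were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over all 63 tests, that is, lists by comparisons. The list of 5 neural genes came from the study itself and is not independent evidence.

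The genes named were fixed by rule before the data were examined. Rlim, Zfp42 and Xist are given in every comparison. Each comparison adds the 8 rising and 8 falling genes of largest log2 fold change that passed the threshold, reached a mean of 1 CPM in the higher group and had no overlap between libraries. Each list adds up to 3 members past the threshold with the smallest p. Gene models with Gm numbers or Rik names were skipped in rank order: 4 in RNF12 wild type against empty vector, and 1 in each of the other comparisons. Not all genes of the rule are printed.

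The test was run on simulated counts with 200 genes changed by known folds before use. The changed genes were drawn only from genes above a minimum mean count. The shares recovered therefore do not cover genes with few counts, such as Xist. At 2-fold, 94.0% of changed genes were recovered in each of the 3 comparisons, with 15017, 15024 and 15007 genes tested in the order given above. At 1.5-fold the shares were 68.7%, 68.7% and 67.2%. Replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom from 2.16 to 48.6, so that none was merged with another. This does not show that they came from separate cultures. Alternatives were other library scalings (DESeq2 size factors, upper quartile, Rlim left out), other filters (none, or CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom, fits with only the groups compared, the replicate number as a block, other list tests (fry, estimated correlation) and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Intervals on counts come from counts summed over the libraries of a group. They cover counting error only and leave out the spread between libraries. Reads were not tagged by molecule, a further source of error that the intervals leave out.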

Results

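Transcriptomes of RNF12-deficient mouse embryonic stem cells were compared after transfection with an empty vector, wild-type RNF12 or the catalytic mutant RNF12 W576Y. RNF12 is an E3 ubiquitin ligase encoded by the X-linked gene Rlim, and the series asks which transcripts depend on its ligase activity. Each group had 3 libraries. Total counts were 41487987, 44268295 and 44871153 for empty vector, 54641514, 39763001 and 39752729 for wild type, and 42642431, 37852339 and 43570528 for the libraries labelled W576Y.

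Rlim, on chromosome X at 103957163 to 103981284 of GRCm38, was at 112 ± 10.9 CPM (SD, n = 3) with empty vector and 225 ± 15.3 CPM with wild-type RNF12. The log2 fold change was 1.01 ± 0.08 (SE), with an adjusted p of 6.69e-05 by edgeR's quasi-likelihood test. In the libraries labelled W576Y, Rlim was at 114 ± 9.01 CPM, a log2 fold change of 0.03 over empty vector with a 95% interval from -0.16 to 0.21 and an edgeR adjusted p of 0.912. The transcript of a transfected mutant was therefore not seen as a rise in Rlim counts in those libraries, and every direction drawn from that label below carries this limit. Gene counts do not separate plasmid transcripts from those of the disrupted gene. Between wild type and the libraries labelled W576Y, catalytic activity and Rlim transcript level differ together.

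**Figure D1:**
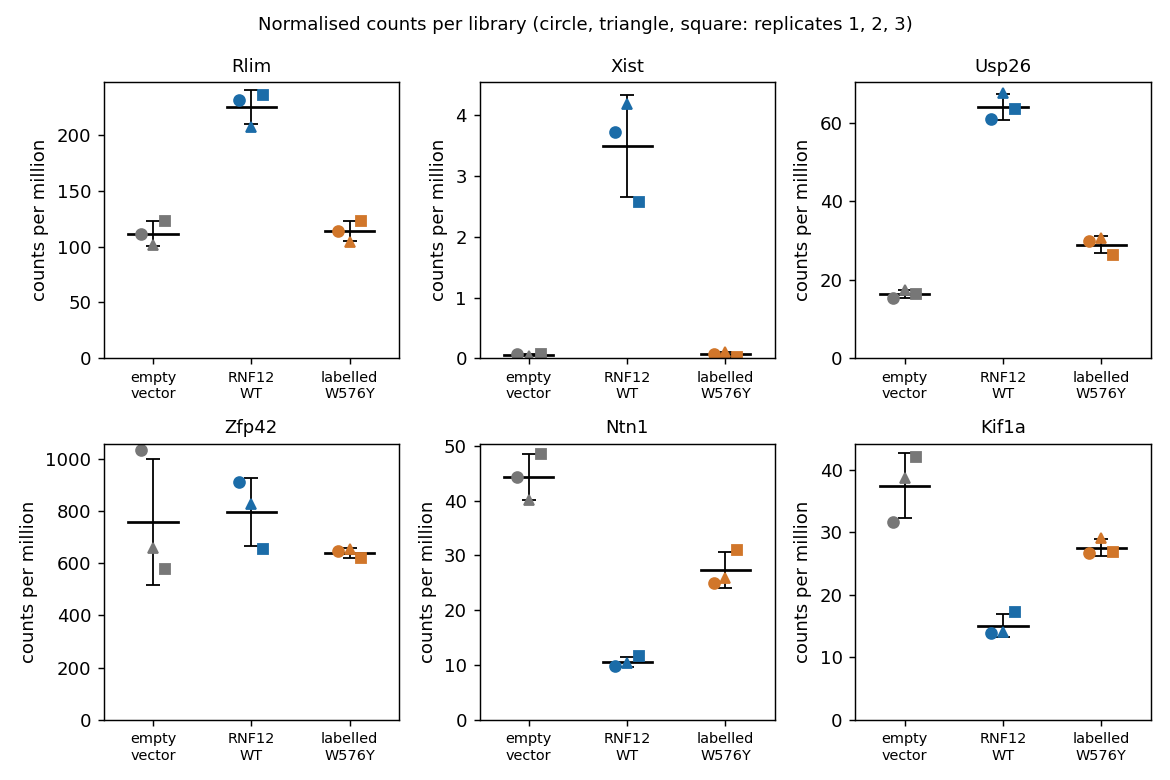
TMM-scaled counts relative to library size (CPM, linear axes from 0) of 6 genes in each library, with the group mean and SD (n = 3). Rlim reached 225 CPM in the wild-type libraries and lay near 112 CPM in the other groups, while Usp26 was intermediate, at 29.0 CPM, in the libraries labelled W576Y.

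The comparison of wild-type RNF12 with empty vector asks what restoring RNF12 changes. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), rose from 8 to 477 counts summed over 3 libraries, a ratio of 56.6 with a 95% counting interval from 28.5 to 132 (edgeR adjusted p = 1.00e-05). Its antisense partner Tsix rose by 1.29 ± 0.20 on the log2 scale. Because the strand setting of the counting is not given, part of that rise may be Xist reads. Tsix had 209 summed counts with empty vector and 328 in the libraries labelled W576Y. Xist had 8 in each, so Tsix counts there did not follow those of Xist. Zfp42, which encodes the RNF12 substrate REX1, was at 756 ± 242 CPM and 796 ± 131 CPM (log2 fold change 0.07, edgeR adjusted p = 0.798). In all, 1942 genes were higher and 1995 lower, of 15121 tested, and 412 and 177 of them changed at least 2-fold.

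More germ cell genes rose than fell with wild-type RNF12. Of 62 tested members, 30 rose, 5 fell and 27 did not pass (adjusted over the list alone, 35 and 5), and camera gave an adjusted p of 1.70e-08. With an estimated correlation the adjusted p was 0.364, and when 1 library was left out 25 to 34 were higher and 2 to 8 lower. Usp26, a deubiquitinase gene on chromosome X at 51753959 to 51801233, rose from 16.4 ± 1.06 to 64.1 ± 3.38 CPM, a log2 fold change of 1.96 ± 0.08. The homeobox genes Rhox13 and Rhox5 rose by 2.02 ± 0.12 and 1.82 ± 0.10. Among the genes of largest rise were Magea8 (4.43 ± 0.37), Pramel3 (3.76 ± 0.27) and Pramel7 (3.69 ± 0.42), members of multi-copy families whose reads can be shared, so these values are uncertain. AI662270 rose by 4.76 ± 0.18, Vnn1 by 3.84 ± 0.48, Pet2 by 3.61 ± 0.34 and the Y-linked gene Usp9y by 3.69 ± 0.29. Summed counts with empty vector were only 10 for Vnn1, 13 for Magea8, 14 for Pet2, 29 for Pramel3 and 35 for Usp9y. The size of these rises is therefore uncertain.

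Most of the neural genes that the study had chosen fell. Of these 5 genes, 4 fell and 1 did not pass (the same adjusted over the list alone), a count that is not independent evidence of direction. Camera gave an adjusted p of 0.0105, and an adjusted p of 0.364 with an estimated correlation. Dll1, a Notch ligand gene on chromosome 17 at 15367354 to 15376872, fell from 12.02 ± 4.96 to 2.90 ± 1.11 CPM (log2 fold change -2.07 ± 0.34). Kif1a, a kinesin gene of axonal transport, fell by 1.32 ± 0.11 on the log2 scale and Gfap, the astrocyte filament gene, by 1.40 ± 0.27. In the wider list of neural development genes, 7 of 48 rose, 13 fell and 28 did not pass (7 and 15 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0805). Its member Ntn1, the netrin-1 guidance gene, fell from 44.2 ± 4.19 to 10.6 ± 0.946 CPM (log2 fold change -2.07 ± 0.11), and Epha4 fell by 0.68 ± 0.05. Neurog1, a proneural factor gene, rose from 7 to 109 summed counts, a ratio of 14.8 with a counting interval from 6.93 to 37.6. Other large falls were those of Myl3 (-2.51 ± 0.49), the elastin gene Eln (-2.09 ± 0.30), Bcl11a (-2.09 ± 0.23), Vrtn (-1.88 ± 0.30) and Ucp1 (-1.88 ± 0.21).

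Pluripotency genes moved both ways, with 8 of 40 naive members higher and 7 lower (camera adjusted p = 0.762). Dppa3 rose by 1.75 ± 0.16 and Fbxo15 by 0.84 ± 0.10, while Lin28a fell by 0.84 ± 0.08. Among formative and primed genes 3 of 28 rose and 9 fell (adjusted p = 0.100), with Zic2 rising by 1.92 ± 0.22 and Sox11 falling by 0.76 ± 0.08. Of mesendoderm genes 5 of 20 rose and 3 fell (adjusted p = 0.922): Hand1 rose by 2.32 ± 0.14, while Cdx1 and T, which encodes Brachyury, fell by 1.70 ± 0.14 and 1.19 ± 0.13. Primitive endoderm genes counted 8 of 22 higher and 3 lower (adjusted p = 0.0809), with Gata6 rising by 1.20 ± 0.24 and Apoe falling by 0.91 ± 0.18. Trophoblast genes counted 6 of 20 higher and 2 lower (adjusted p = 0.0809). In the imprinted list 4 of 30 rose and 7 fell (adjusted p = 0.933), among them Sfmbt2 (2.17 ± 0.07) and H19 (1.53 ± 0.08), which rose, and Rian (-0.58 ± 0.05), which fell. Nodal and BMP pathway genes counted 6 of 27 higher and 4 lower (adjusted p = 0.864), with Ctgf rising by 1.58 ± 0.19 and Lefty2 by 0.86 ± 0.12. When 1 library was left out, the counts of higher and lower members ranged from 7 to 17 and 3 to 12 (naive), 1 to 5 and 8 to 10 (formative and primed), 1 to 5 and 2 to 6 (mesendoderm), 3 to 8 and 1 to 4 (primitive endoderm), 3 to 8 and 0 to 3 (trophoblast), 4 to 13 and 4 to 9 (imprinted), and 5 to 8 and 3 to 9 (Nodal and BMP).

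The list of X-inactivation genes passed camera (adjusted p = 5.57e-04, and 0.364 with an estimated correlation), with 7 of 13 members higher, Xist, Tsix and Rlim among them, and 4 to 9 when 1 library was left out. Rlim is the transfected gene itself, so this list is not independent of the transfection. The list mean log2 fold change was 0.90 and the median 0.28. Genes of the 2-cell stage had 5 of 34 members higher and none lower (camera adjusted p = 6.22e-05, and 0.608 with an estimated correlation), and 3 to 32 higher when 1 library was left out. Their mean deviation was uneven within groups: 0.55 in empty-vector replicate 1 but -0.66 and -1.14 in replicates 2 and 3, and 0.97 and 0.95 in wild-type replicates 1 and 2 but -0.08 in replicate 3. The remaining lists did not pass camera. Counts of higher and lower members were 8 and 4 of 30 for cell cycle genes, 2 and 8 of 18 for fibroblast genes, 2 and 6 of 23 for interferon genes and 0 and 5 of 28 for p53 targets. They were 5 and 0 of 31 for proteasome genes, 5 and 2 of 18 for splicing kinases and SR proteins, 6 and 4 of 30 for stress genes and 1 and 0 of 11 for replication-dependent histones. When 1 library was left out, these counts ranged from 5 to 9 and 2 to 12 (cell cycle), 1 to 2 and 5 to 8 (fibroblast), 2 to 4 and 3 to 7 (interferon), 0 to 2 and 1 to 15 (p53), 0 to 13 and 0 (proteasome), 0 to 9 and 0 to 3 (splicing), 3 to 10 and 3 to 5 (stress), and 0 to 1 and 0 (histones). Of X-linked genes, 130 of 577 (22.5%) rose, against 12.5% of other genes (Fisher's exact test, 2-sided, odds ratio 2.04, adjusted p over 6 tests = 1.75e-10, with genes not independent), and 58 fell (31 to 95 when 1 library was left out). The mean X-linked log2 fold change was 0.29 and the median 0.09 (camera adjusted p = 0.00524, and 0.364 with an estimated correlation). Of the X-linked genes, 33 were also in another list, such as Usp26 and Rhox5 among germ cell genes. The X-linked and germ cell results are therefore not separate in any comparison.

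The number of called genes depended on single libraries. It was 6708 without empty-vector replicate 1, 2171 and 2040 without wild-type replicate 1 or 2, and 2566 without empty-vector replicate 2. It was 2212 with only these 6 libraries in the fit. In the authors' deposited table, 1369 genes were higher and 1578 lower at an adjusted p under 0.05, and 2924 of their calls were shared here in the same direction.

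**Figure D2:**
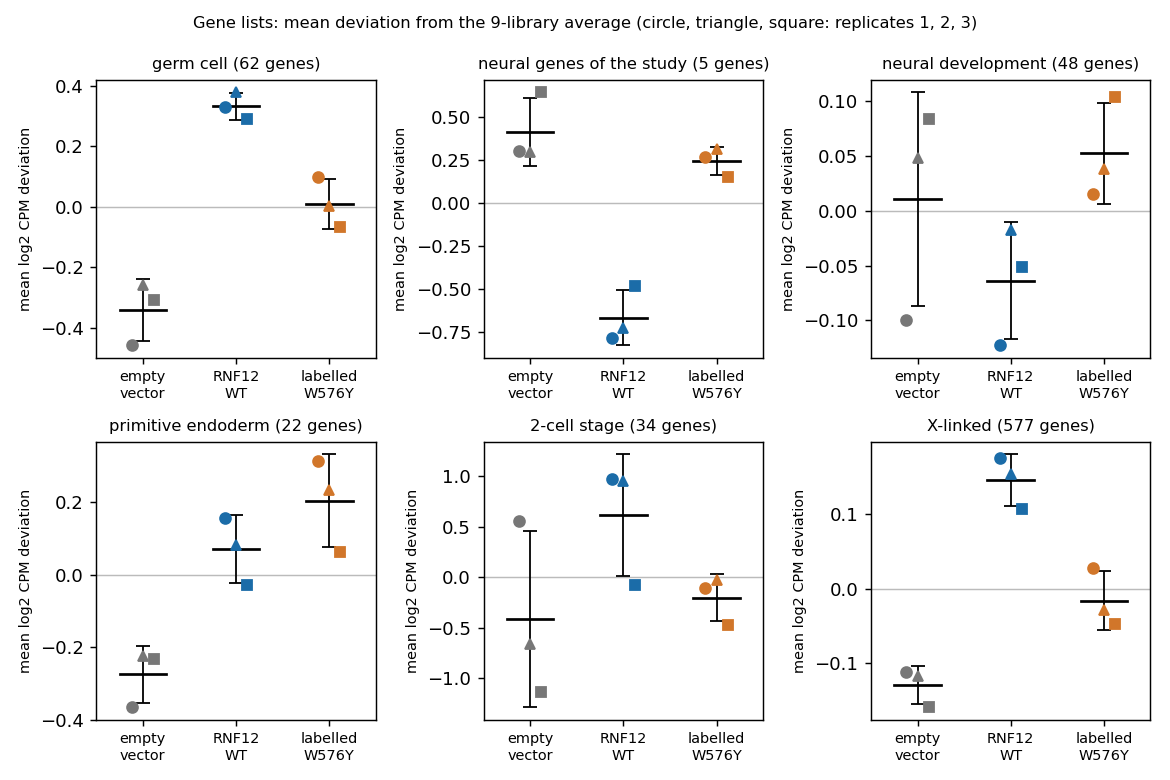
Mean deviation of log2 CPM from the average of the 9 libraries, over the genes of 6 lists, with group mean and SD (n = 3). Germ cell genes were highest in the wild-type libraries, and 2-cell genes ranged from 0.55 to -1.14 among the empty-vector libraries.

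The comparison of the libraries labelled W576Y with wild type asks which of these transcripts depend on catalysis, with the limit on Rlim level given above. Xist was at 8 summed counts against 477, a ratio of 0.0181 with a counting interval from 0.00779 to 0.0360 (edgeR adjusted p = 6.38e-05). Rlim was lower by 0.98 ± 0.08 on the log2 scale, and Zfp42 did not pass (log2 fold change -0.31, edgeR adjusted p = 0.279). In all, 790 genes were higher and 757 lower, and 42 and 146 of them differed at least 2-fold.

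Of germ cell genes, more were lower than higher in the libraries labelled W576Y, with 18 of 62 lower, 1 higher and 43 not past the threshold (26 and 4 adjusted over the list alone; camera adjusted p = 2.46e-04, and 0.448 with an estimated correlation). The 18 lower and 1 higher became 8 to 27 and 0 to 9 when 1 library was left out. Usp26 was lower by 1.14 ± 0.07, Pramel3 by 2.55 ± 0.24 and Usp9y by 2.54 ± 0.25 on the log2 scale. Pet2 (-3.15 ± 0.32), Trim43a (-2.83 ± 0.52) and Magea4 (-2.59 ± 0.23) were also among the largest differences. So were AI662270 (-2.50 ± 0.15) and Magea8 (-2.42 ± 0.29). The same caution on multi-copy families applies. Pet2 and Trim43a had only 19 and 34 summed counts in the libraries labelled W576Y. Sfmbt2 and H19 were lower by 1.06 ± 0.07 and 1.33 ± 0.08, and Dppa3, Fbxo15 and Nanog by 1.61 ± 0.16, 0.82 ± 0.10 and 0.42 ± 0.07.

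Of the 5 study-chosen neural genes, 3 were higher in the libraries labelled W576Y and none lower (4 and 0 adjusted over the list alone, again not independent; camera adjusted p = 0.00559, and 0.364 with an estimated correlation), and 1 to 4 were higher when 1 library was left out. Dll1 was higher by 1.83 ± 0.34, Kif1a by 0.87 ± 0.11 and the netrin receptor gene Unc5a by 0.86 ± 0.20. The wider neural list passed camera (adjusted p = 0.0235, and 0.445 with an estimated correlation), with 7 of 48 higher and 3 lower (3 to 15 and 2 to 5 when 1 library was left out). It lost its call without wild-type replicate 3 or W576Y-labelled replicate 3, where the highest adjusted p was 0.0611. Ntn1 was higher by 1.37 ± 0.11, L1cam by 0.57 ± 0.07 and Epha4 by 0.42 ± 0.05. Eln, Cdh22, Dnahc8 and Cdx1 were higher by 1.51 ± 0.30, 1.45 ± 0.25, 1.30 ± 0.20 and 1.17 ± 0.15.

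Other lists passed camera here with small mean differences or few called members. Proteasome genes had a mean log2 fold change of -0.11 with 1 of 31 members lower (adjusted p = 0.00524, and 0.608 with an estimated correlation), and the call was lost without wild-type replicate 1 (adjusted p = 0.0641). The number of lower proteasome members was 0 to 10 when 1 library was left out. Splicing kinases and SR proteins had 5 of 18 lower and 1 higher (adjusted p = 0.0105, and 0.365 with an estimated correlation), and 0 to 11 lower and 0 to 2 higher when 1 library was left out. Stress genes had 6 of 30 lower and 1 higher (adjusted p = 0.0224, and 0.501 with an estimated correlation), and 1 to 10 lower and 0 to 2 higher when 1 library was left out. Atf4 was lower by 0.97 ± 0.15. Genes of the 2-cell stage had 5 of 34 lower (adjusted p = 1.04e-04, and 0.608 with an estimated correlation), and 1 to 21 when 1 library was left out. X-inactivation genes had 4 of 13 lower (adjusted p = 2.20e-04, and 0.364 with an estimated correlation), and 2 to 6 when 1 library was left out. Xist and the transfected gene Rlim were among the 4, so this list is not independent of the transfection. Its mean log2 fold change was -0.82 and its median -0.31. X-linked genes had a mean of -0.18 (adjusted p = 0.0340, and 0.364 with an estimated correlation), with 70 of 577 lower and 16 higher. Leaving out 1 library gave 28 to 121 lower and 3 to 58 higher. The camera adjusted p was 0.0607 without empty-vector replicate 1, 0.0589 without W576Y-labelled replicate 2 and 0.0565 without wild-type replicate 3.

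This count also rested on single libraries. It was 4610 without empty-vector replicate 1 and 2928 without wild-type replicate 3. Without wild-type replicate 1 or 2 it was 325 or 270, and without W576Y-labelled replicate 1, 2 or 3 it was 368, 294 or 303. DESeq2 called 2454 genes, and the fit to only these 6 libraries called 3842. The authors' deposited table had 1936 higher and 1763 lower genes. Of the 61 called genes under the naming rule, 31 lost their call without at least 1 library, Dll1, Eln, Cdh22, Unc5a, Trim43a and Nanog among them.

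Genes past the threshold in both comparisons with opposite signs numbered 1334, of which 659 were highest and 675 lowest in the wild-type libraries. Independent lists of these sizes would share 97.2 and 104 genes, a value that leaves out the shared libraries. Simulated data without group effects shared 0 genes, but they held only 0.6 calls on average over the 3 comparisons, so they give no chance overlap for lists of this size. Both comparisons use the same wild-type libraries, which 3 libraries do not allow to be split, so part of the excess may come from sharing them. Across genes, which are not independent replicates, the log2 fold changes of wild type over empty vector and over the libraries labelled W576Y had r = 0.823 against 0.499 simulated, and a covariance of 0.136 against 0.0160. The simulated values assume the same spread in every group. Xist, Usp26, Sfmbt2 and H19 were in the first set and Dll1, Ntn1, Kif1a and Epha4 in the second. The number was 3889 without empty-vector replicate 1 and 2445 without wild-type replicate 3. It was 305 and 254 without wild-type replicates 1 and 2, and 358, 287 and 293 without W576Y-labelled replicates 1, 2 and 3.

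The comparison of the libraries labelled W576Y with empty vector asks what the mutant changes over no RNF12. Of 15121 genes, 65 were higher and 50 lower, and 19 and 4 of them differed at least 2-fold. Xist stood at 8 summed counts in each group (ratio 1.03, counting interval 0.336 to 3.14), and Zfp42 did not pass (log2 fold change -0.24, edgeR adjusted p = 0.571). Of the called genes, 60 were also higher and 50 also lower in wild type than in empty vector, and 5 were not called there. Independent lists would share 8.35 and 6.60. The empty-vector libraries are common to both comparisons, and r across genes was 0.636 against 0.498 simulated, with a covariance of 0.0771 against 0.0160. The simulation gave every group the same spread, so these values do not separate an effect from the sharing of libraries.

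Of germ cell genes, 6 of 62 rose and none fell (28 and 1 adjusted over the list alone; camera adjusted p = 6.30e-10, and 0.364 with an estimated correlation), and 3 to 10 rose when 1 library was left out. Usp26 was at 29.0 ± 2.23 CPM against 16.4 ± 1.06 (log2 fold change 0.82 ± 0.08, edgeR adjusted p = 0.00145). Rhox13 rose by 1.34 ± 0.12 and Rhox5 by 1.25 ± 0.10. Primitive endoderm genes counted 2 of 22 higher and none lower (12 and 0 adjusted over the list alone; camera adjusted p = 2.19e-06, and 0.364 with an estimated correlation), and 1 to 3 were higher when 1 library was left out. Sparc, a matrix protein gene, rose by 0.50 ± 0.06, and Gata6 by 1.28 ± 0.24. AI662270 (2.27 ± 0.19), Hand1 (1.61 ± 0.15), Inhbb (1.42 ± 0.22), Peg12 (1.37 ± 0.17), Kdm5d (1.32 ± 0.15) and Sfmbt2 (1.11 ± 0.07) also rose. Bcl11a (-1.60 ± 0.22), Ano4 (-1.18 ± 0.18), Zfp608 (-1.07 ± 0.18), Trh (-1.001 ± 0.142), Actn3 (-0.90 ± 0.13) and Ntn1 (-0.70 ± 0.10) fell. None of the 5 study-chosen neural genes passed (1 was lower adjusted over the list alone).

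Formative and primed genes passed camera (adjusted p = 0.0340, and 0.413 with an estimated correlation) with 2 of 28 lower, and splicing kinases and SR proteins did so (adjusted p = 0.0460, and 0.457 with an estimated correlation) with no member past the threshold. The formative members that were lower numbered 0 to 3 when 1 library was left out. Leaving out 1 library ended the first call for 4 libraries (highest adjusted p = 0.108) and the second for 4 (highest adjusted p = 0.189). X-linked genes had a mean of 0.11 (adjusted p = 0.0154, and 0.364 with an estimated correlation), with 11 of 577 higher and 4 lower. Leaving out 1 library gave 6 to 17 higher and 1 to 7 lower, and the adjusted p was 0.0798 without W576Y-labelled replicate 1. The count of 115 genes was 298 without empty-vector replicate 1, 46 without empty-vector replicate 2 and 50 without wild-type replicate 2. It was 24, 23 and 32 without W576Y-labelled replicates 1, 2 and 3. DESeq2 called 613, and the fit to only these 6 libraries called 38. Of the 27 called genes under the naming rule, 18 lost their call without at least 1 library, Gata6, Inhbb, Bcl11a, Ano4, Zfp608, Trh, Actn3 and Ntn1 among them.

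**Figure D3:**
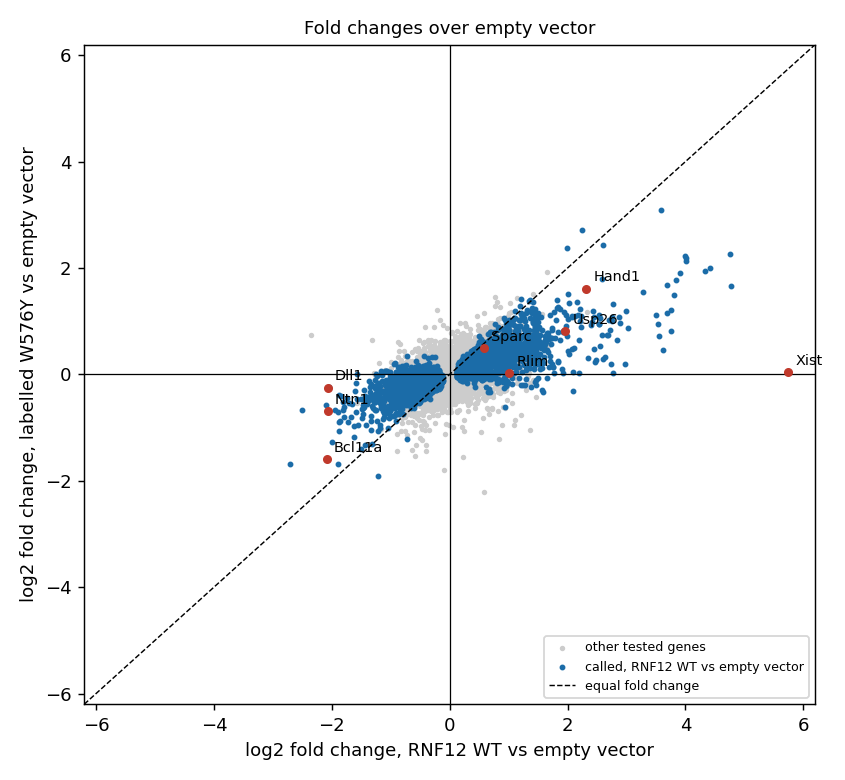
Log2 fold change over empty vector of each of the 15121 tested genes in the libraries labelled W576Y (vertical) against wild-type RNF12 (horizontal), with genes called for wild type in blue. Xist lay at 5.75 and 0.04, Usp26 at 1.96 and 0.82, and Bcl11a at -2.09 and -1.60.

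Of the 106 genes under the naming rule, 31 span an annotated gene on the other strand, Xist, Tsix, Dll1, Ntn1, Unc5a, Gfap, Eln and Bcl11a among them. The overlap is of whole gene spans, not of exons. Without a stated strand setting, their reads may not be fully separated from those of the overlapping gene.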

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

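Alternative scalings, filters and limma-voom kept the 4 counts of genes within 1.5 times, but upper-quartile scaling turned 1942 higher and 1995 lower genes of wild type against empty vector into 2224 and 1743. DESeq2 raised the count of W576Y-labelled against wild type from 1547 to 2454 and against empty vector from 115 to 613. Fits to only the groups compared gave 2212, 3842 and 38 in place of 3937, 1547 and 115. Leaving out 1 library gave 2040 to 6708 genes for wild type against empty vector and 270 to 4610 for W576Y-labelled against wild type. It gave 23 to 298 for W576Y-labelled against empty vector and 254 to 3889 activity-dependent genes. The fit shares 1 estimate of spread over the groups, so a library can change the count of a comparison it is not part of. Leaving out empty-vector replicate 1 gave the 4610 genes for W576Y-labelled against wild type. The causes of the ranges were not tested further.

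With the replicate number as a block, edgeR gave 4743, 2763 and 206 genes and 2224 activity-dependent genes, and DESeq2 gave 3893, 2542 and 468. The numbers were not taken to pair the libraries, because the sample titles repeat them in each group without saying what they mark. Of same-numbered pairs, 5 of 9 had deviations correlated above 0.1 (from -0.16 to 0.46). For 7 of 9 libraries the best correlation was with their own number. This is a hint of pairing from the data, which the labels do not state.

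None of the 16 list calls held with an estimated correlation (lowest adjusted p 0.364). The self-contained test fry kept 10 of the 16 and lost 6, with adjusted p from 0.0650 to 0.172. The 6 were 2-cell genes in both comparisons with wild type and proteasome and stress genes against wild type. The others were formative genes and splicing factors against empty vector. Fry called 22 list tests in all, some of which camera did not call. For wild type against empty vector, these included fibroblast (fry adjusted p = 0.00124), formative (0.0143) and neural development genes (0.0284), lower. Trophoblast (0.00180), imprinted (0.00807), histone (0.0166) and primitive endoderm genes (0.0396) were called higher by fry there. X-linked genes lost their calls with an estimated correlation, with means of 0.29, -0.18 and 0.11 (adjusted p = 0.364), and leaving out 1 library gave means of -0.20 to -0.16 for W576Y-labelled against wild type and 0.0859 to 0.141 against empty vector, with 3 calls and 1 call lost. Of called genes under the naming rule, 58 of 68, 30 of 61 and 9 of 27 kept their call under every alternative that gave a value, and no called gene changed sign.

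Only values that were not called changed sign. Against empty vector in the libraries labelled W576Y, Xist was at -0.0856 with limma-voom. Leaving out 1 library moved Xist from -0.418 to 0.446, Rlim from -0.0405 to 0.104, Zfp42 from -0.397 to 0.0505 and the means of cell cycle (-0.0361 to 0.0187), naive (-0.0067 to 0.0353), p53 (-0.0661 to 0.0342), proteasome (-0.054 to 0.0168), stress (-0.0785 to 8e-04) and 2-cell genes (-0.273 to 0.741). It moved Zfp42 from -0.0901 to 0.364 and cell cycle genes from -0.0245 to 0.0245 in wild type against empty vector, and cell cycle genes from -0.0171 to 0.0013 and formative genes from -0.0382 to 0.0207 in W576Y-labelled against wild type.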

Other observations

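The tests of the Y-linked genes, of Rlim and of the intermediate genes were chosen after the results were seen, and what the splits of the libraries would show was written only after they were run. Of 8 Y-linked genes tested, which were not a fixed list, 7 were called higher with wild-type RNF12, with log2 fold changes from 0.61 (Uty) to 3.69 (Usp9y), Kdm5d at 2.78 and Uba1y at 1.42. Eif2s3y did not pass (0.13, edgeR adjusted p = 0.0944). In the libraries labelled W576Y only Kdm5d of these passed against empty vector (1.32).

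More Y chromosome per cell would raise all of these genes alike, yet the upper limit for Eif2s3y was 0.24, below the smallest called rise of 0.61. Reads shared with X-linked paralogs would not raise a Y-linked gene above its paralog. In 7 of 7 pairs, the lower limit of the Y-linked gene lay above the upper limit of the paralog. These pairs were chosen because their Y-linked gene was called higher. Eif2s3y was left out, and its lower limit of 0.01 lay below the upper limit of its paralog Eif2s3x, 0.09. The log2 fold changes of the paralogs Usp9x and Kdm5c were 0.07 and 0.04. Zfx was the paralog of both Zfy1 and Zfy2 and itself rose by 0.25 (edgeR adjusted p = 0.0127). No biological explanation was tested.

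Rlim in the libraries labelled W576Y stood at the empty-vector level. If these were empty-vector libraries of the same experiment, few genes would differ. In the data 115 did, against a highest count of 1 over 20 simulations without effects. The simulations held no library standing apart as empty-vector replicate 1 does. Without that library, however, all 115 calls were kept and 298 genes were called, so it did not create the calls. The count was 23 to 298 when 1 library was left out. These values argue against this explanation, although no simulation was run with unequal spread. Against wild type, Rlim in these libraries had a log2 fold change of -0.98 (edgeR adjusted p = 3.77e-04), so total Rlim transcript was lower. Whether the mutant plasmid itself gave less transcript stays open. The upper limit of the Rlim log2 fold change over empty vector was 0.21, and plasmid and endogenous reads are not separated. Less transcript and a loss of catalytic activity therefore cannot be told apart.

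Many genes in those libraries lay between the other groups. The 412 genes that rose at least 2-fold with wild type reached a median of 28.3% of that rise (quartiles 15.6% and 45.4%). They were chosen on the same empty-vector libraries that set the baseline, so part of this share may follow from the choice. The share without an effect was not computed. Carry-over of wild-type material would bring Xist too, but Xist reached 0.0902%, with an upper limit of 2.86%. The covariance of the fold changes was 0.0611 above the value simulated with shared empty-vector libraries and no effect. That simulation gave every group the same spread. In the data, chi-square per degree of freedom reached 48.6 within empty vector, 25.5 within wild type and 4.41 within the libraries labelled W576Y. Extra spread in the shared libraries would raise this covariance, so sharing them is not excluded. No biological explanation was tested for this pattern either.

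For wild type against empty vector the real split gave 3937 genes, and another split gave 2947, joining empty-vector replicate 1 with wild-type replicates 1 and 2. The real split was 1 of 10 with a count as large. For the other comparisons the real counts were 1547 and 115 and the highest of the others 0, each 1 of 10. With 10 splits a share under 0.05 cannot be reached. For activity-dependent genes, 3 of 100 drawn splits, the real one included, gave at least 1334, the highest of the others being 1761. That share is under 0.05, but splits with counts this large point to a structure among the libraries beyond the groups. Chi-square per degree of freedom was 41.2 and 48.6 between empty-vector replicate 1 and replicates 2 and 3, and 4.89 between the latter. It was 25.5 and 14.0 between wild-type replicate 3 and replicates 1 and 2, and 4.69 between the latter.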
